A study of Mus musculus with 16 samples.

How the data were processed

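Genomic DNA of mouse splenic B cells (CD43-, 129 background, preassembled IgH and IgK loci) was studied after 4 days with anti-CD40 (1 ng/mL) and IL-4 (20 ng/mL). Junctions to a 5′ Sμ bait were captured by linear amplification with a biotinylated primer and nested PCR, germ-line sequence was removed with AflII, and libraries were sequenced on a MiSeq. Groups were wild type (4 libraries), Xrcc4-/- (4), DNA-PKcs-/- (4) and DNA-PKcs KD/KD (2). A further control group of 2 libraries enters the controls together with wild type; its own values and its comparison with wild type are not reported here. Per the labels, the DNA-PKcs KD/KD cells differed from wild type in a further respect of genotype and were not purified before stimulation.

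The authors aligned the reads with Bowtie2 (version not stated) to mm9 in which the IgH switch region had been replaced by the 129 sequence, called mm9sr; other filters were not stated. The deposited workbooks hold, per library, whole-number junction counts per region and per length of overlap or insertion, lists with 1 line per junction, junction counts per bin of the switch regions and strand, and mutation counts by base change in the bait part of the reads. All these deposited counts are raw, without normalization, as the sums of the values showed: the authors' bin counts add up to the junctions listed in the same sheet. Pooled workbooks per genotype hold the same sheets, and how the authors pooled the libraries was not stated. Of 358 sheets or columns, 229 were used, among them 47 bin count sheets. The other 129 repeat used values, such as the union of the region lists or fractions of the same counts, or exist for part of the libraries.

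A junction was called blunt when bait and prey alignments abut on the read, and otherwise has microhomology (overlap) or an insertion of the length in bp between them. Insertions over 30 bp were left out of the main values because the lists of some libraries hold none. The 131 blank lines in the lists were not analysed here. Strand was read as orientation relative to the bait, with the strand of deletional joining as deletional. Coordinates on chromosome 12 in the switch regions are those of mm9sr and count from 1. Outside IgH, the lists were compared with the GENCODE vM1 annotation (NCBIM37, the same assembly as mm9). Sequencing runs were taken from the read names.

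Library totals, in junctions with insertions of at most 30 bp, were 949, 506 and 667 for wild-type replicates 1, 2 and 4, 608, 1202, 4941 and 1294 for Xrcc4-/- 1 to 4, 2527, 2989, 126 and 185 for DNA-PKcs-/- 1 to 4, and 325 and 845 for DNA-PKcs KD/KD 1 and 2. Single shares carry Wilson 95% intervals, and a count of 0 is given the limit of 3 counts. Identical junctions shared by 2 libraries made up at most 4% of the smaller library.

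Per library, the measures were the share of junctions per region, Sε over Sε plus Sγ1, blunt junctions and microhomology of 4 bp or more (with other structural measures in the same family of tests), the deletional share, the share outside the interval holding the central 95% of the controls' pooled positions (each control library judged against the others), the median position, mutations per 10000 bases of the bait and per 10000 of each base, the share of these mutations at G, and the share of junctions outside IgH with microhomology over 10 bp. A library entered for a region with at least 20 junctions there, but no minimum applied to the share with microhomology over 10 bp outside IgH. Bait mutations were compared between sheets made from IgH junctions. Group means were compared in 7 comparisons by two-sided exact permutation tests of the difference of means, with Benjamini-Hochberg adjustment within each family (42 tests of region usage, 209 of structure, 21 of orientation, 42 of position, 42 of bait mutations and 14 of long microhomology). A difference was called at an adjusted p of at most 0.05. The tests with an unadjusted exact p under 0.05 numbered 12, 52, 6, 11, 2 and 0 in that order, and 4 position tests passed after adjustment. Tests used Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1, and figures matplotlib 3.10.9.

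Junctions per bin of 500 bp and orientation were tested in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood test, 15 libraries, all groups in 1 fit, library size the junctions in Sμ, Sγ1 and Sε, no further normalization, bins of at least 20 junctions). Each mutant group was contrasted with the controls. Values relative to a library total are compositional, and TMM normalization was run as an alternative. On simulated counts for the same libraries, with 30 of 88 bins changed and a dispersion of 0.1, a 4-fold change was recovered in 70% of changed bins for DNA-PKcs-/-, 66.7% for DNA-PKcs KD/KD and 86.7% for Xrcc4-/-, with 2, 1 and 1 false calls. A 2-fold change was recovered in 23.3%, 0% and 13.3%. Simulated data without changes gave 0 calls. The simulated changes were split evenly between rises and falls, and the dispersion was not compared with that of the data. The simulation therefore does not cover rises that follow from a one-sided fall in Sε.

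Named were the 5 regions in every comparison, the 5 bins with the largest rise and the 5 with the largest fall past the threshold in each comparison, the 5 windows of 1 Mb outside IgH with junctions in the most libraries, and loci chosen in advance. Folds of bins are ratios of pooled counts with exact 95% intervals; where a group had 0 junctions, the fold is a bound with 3 counts over that group. Comparisons, tests, the naming rule and most alternatives were fixed before the data were examined: other control groups, pooling of junctions, IgH junctions as denominator, collapsing of duplicates, other minimum counts (10 and 50) and microhomology lengths, bins of 200 and 1000 bp, TMM, DESeq2 1.42.0, no filter, a replicate block, no libraries under 500 junctions for region usage and bins, and leaving out each library. Chosen after the data were examined were the limit of 30 bp on insertions and its removal, sequencing run as a block or covariate, the authors' pooled counts, the limit of 500 junctions for the other measures, the replicate block for long microhomology, the flank of 10 kb around loci and the gap of 2 Mb that joins the histone genes. Junctions in the authors' pools were aligned to the NCBIM37 chromosome 12 with bwa 0.7.19 to read mapping quality, since the 129 sequence of the switch region was not at hand.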

Results

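Junctions of immunoglobulin class switch recombination were sequenced from activated mouse splenic B cells of several genotypes by high-throughput genome-wide translocation sequencing (HTGTS). In this assay a biotinylated primer in the 5′ part of Sμ, the bait, is extended into whatever sequence has been joined to it, and each junction gives the position and orientation of the joined sequence, the prey. The 16 libraries comprised 4 of wild-type cells, 2 further control libraries, 4 of Xrcc4-/- cells, which lack a core end-joining factor, 4 of DNA-PKcs-/- cells and 2 of DNA-PKcs KD/KD cells, which carry a kinase-dead protein. The cells were cultured for 4 days with anti-CD40 and IL-4, which induce switching to Sγ1 and Sε. The DNA-PKcs KD/KD cells differed from the wild-type cells in a further respect of genotype and were stimulated without the purification of B cells used for the other groups, so the kinase-dead allele is not the only difference from the controls. The wild-type libraries and the 2 further libraries together served as the controls.

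For 15 libraries the junctions per region were counted. They held 126 to 4941 junctions each (median 949, total 21685) with insertions of at most 30 bp. DNA-PKcs-/- replicates 3 and 4 held 126 and 185 junctions and DNA-PKcs KD/KD replicate 1 held 325; every other library held over 500. For wild-type replicate 3 only positions in Sμ (1430) and Sγ1 (1061) were analysed, so the controls number 5 or 6 depending on the measure. The read names assign the libraries to 4 sequencing runs of 9, 4, 2 and 1 libraries. Run 1 holds 3 control libraries, both DNA-PKcs KD/KD libraries, 3 of the Xrcc4-/- libraries and 1 DNA-PKcs-/- library. Run 2 holds 1 wild-type and 3 DNA-PKcs-/- libraries, run 3 holds 1 wild-type and 1 Xrcc4-/- library, and run 4 holds 1 of the further control libraries. Differences within runs therefore often rest on 1 library on a side. The reads carry no molecular identifiers, so all intervals and limits cover counting error only.

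The first question, stated in the design of the series, was how efficiently the mutant cells switched, and to which isotype. The shares given here are relative to each library's own junctions. They compare the regions joined and do not measure how many cells switched. Sε held 39.9% ± 6.5 (SD, n = 5) of the junctions of the control libraries. It held 8.52% ± 5.3 (SD, n = 4) in DNA-PKcs-/-, 4.41% ± 2.9 (SD, n = 2) in DNA-PKcs KD/KD and 3.87% ± 2.1 (SD, n = 4) in Xrcc4-/-. No library of these 3 groups overlapped the controls. Each p was the smallest its design allows in a two-sided exact permutation test, 0.00794 for DNA-PKcs-/- and for Xrcc4-/- and 0.0476 for DNA-PKcs KD/KD. After Benjamini-Hochberg adjustment over the 42 tests of region usage the values were 0.0556, 0.0556 and 0.167, so none passed 0.05. Within run 1 the Sε share differed from the controls by -34.6 percentage points in DNA-PKcs-/-, -31.9 in DNA-PKcs KD/KD and -33.1 in Xrcc4-/-, and within run 2 by -33.0 in DNA-PKcs-/-. In the authors' pooled lists, which hold more Sγ1 junctions and carry no replicates, the Sε share was 26.0% in wild type, and the differences from the controls in the same order of groups were -20.5, -22.8 and -22.0, against -31.4, -35.5 and -36.0 between library means. The wild-type pool holds 15930 junctions against 2122 in the wild-type libraries with counts, which lack replicate 3. The sets of control junctions compared therefore also differ.

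**Figure D1:**
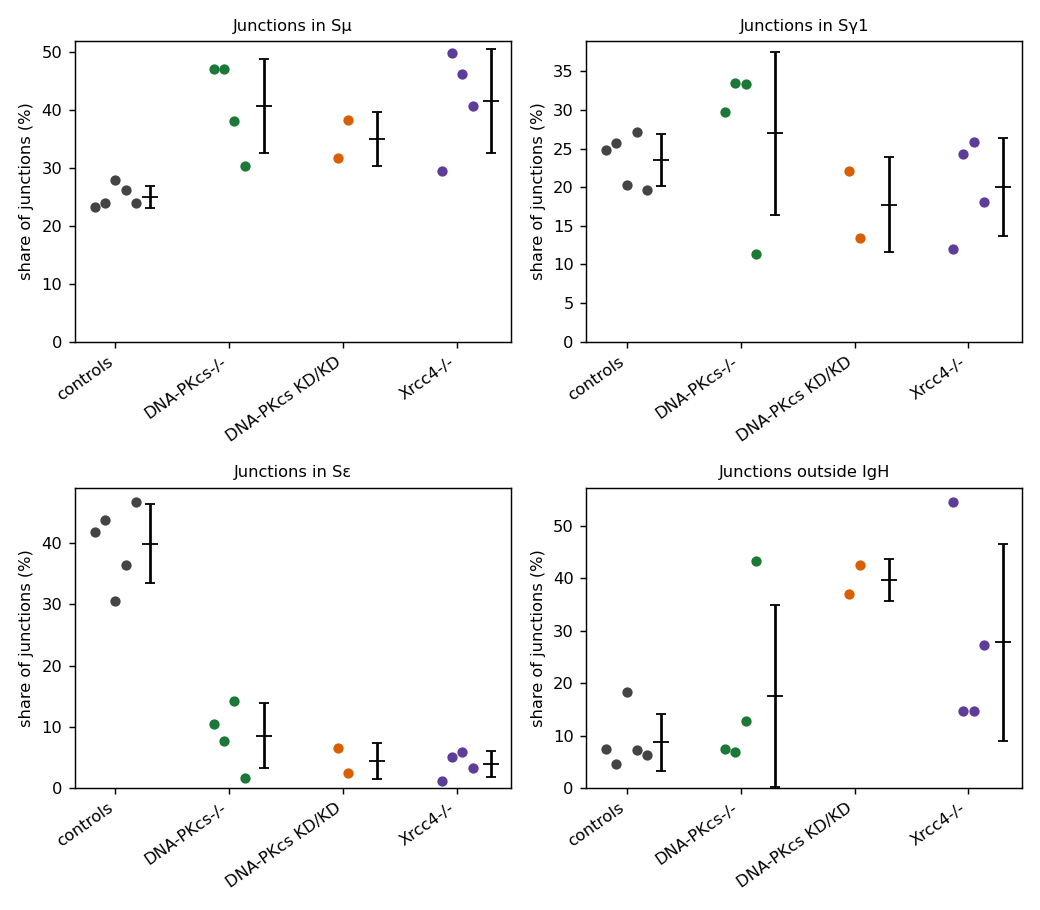
Share of each library's junctions (%) in Sμ, Sγ1, Sε and outside IgH, by group. Points are libraries and bars are means with SD; in the Sε panel every mutant library lies below every control library, with means of 39.9% in the controls and 8.52%, 4.41% and 3.87% in DNA-PKcs-/-, DNA-PKcs KD/KD and Xrcc4-/-.

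Junctions within Sμ made up 25.0% ± 1.9 (SD, n = 5) in the controls, 40.6% ± 8.1 (SD, n = 4) in DNA-PKcs-/-, 34.96% ± 4.6 (SD, n = 2) in DNA-PKcs KD/KD and 41.6% ± 8.9 (SD, n = 4) in Xrcc4-/-. These libraries again did not overlap the controls, with the same exact and adjusted p as for Sε. Compared within run 1, the Sμ differences were 4.49, 9.18 and 14.3 percentage points in the same order of groups, and within run 2 the difference was 20.2 in DNA-PKcs-/-. In the pooled lists they were 11.6, 15.5 and 17.6. Sγ1 shares overlapped between the controls (23.5% ± 3.4, SD, n = 5), DNA-PKcs-/- (27.0% ± 11, SD, n = 4), DNA-PKcs KD/KD (17.8% ± 6.2, SD, n = 2) and Xrcc4-/- (20.1% ± 6.3, SD, n = 4). Their exact permutation p-values against the controls were 0.532, 0.238 and 0.333, with adjusted values of 0.723, 0.588 and 0.672. Within run 1 the Sγ1 differences were -12.7, -6.32 and -5.96 percentage points, and within run 2 the difference was 6.52 in DNA-PKcs-/-, so the direction in DNA-PKcs-/- differed between runs. Leaving out 1 library gave differences of 1.30 to 8.71 in DNA-PKcs-/-, -10.1 to -1.36 in DNA-PKcs KD/KD and -5.38 to -0.757 in Xrcc4-/-. The library lists hold fewer Sγ1 junctions than the authors' pooled lists of the same genotypes, which hold 2.83 to 3.70 times as many in the 3 mutant groups. These junctions enter the total of every share, so the shares of all regions apply to the library lists.

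Because shares of 1 library sum to the whole, a lower Sε share raises the others. Sε as a share of Sε plus Sγ1 compares the target isotypes directly. It was 62.7% ± 4.9 (SD, n = 5) in the controls, 21.8% ± 7.8 (SD, n = 4) in DNA-PKcs-/-, 18.8% ± 5.3 (SD, n = 2) in DNA-PKcs KD/KD and 15.0% ± 4.4 (SD, n = 4) in Xrcc4-/-, without overlap and with the exact and adjusted p given for the Sε share. Restricted to run 1, the differences were -47.6, -41.2 and -46.2 percentage points, and within run 2 the difference was -38.2 in DNA-PKcs-/-. In the authors' pooled lists, which carry no replicates and more Sγ1 junctions, the same ratio was 33.8% in wild type, 7.34% in DNA-PKcs-/-, 6.71% in DNA-PKcs KD/KD and 7.18% in Xrcc4-/-. The wild-type pool is also not limited to the libraries behind the mean of the controls.

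The rest of IgH held 2.79% ± 0.51 (SD, n = 5) of the junctions in the controls, 6.28% ± 5.1 (SD, n = 4) in DNA-PKcs-/-, 3.16% ± 0.55 (SD, n = 2) in DNA-PKcs KD/KD and 6.70% ± 3.2 (SD, n = 4) in Xrcc4-/-, all overlapping the controls. The exact permutation p-values were 0.0794, 0.429 and 0.0317 and the adjusted ones 0.256, 0.692 and 0.167. Among libraries of run 1, the differences were 10.6, 0.271 and 3.57 percentage points, and within run 2 the difference was 1.89 in DNA-PKcs-/-. The DNA-PKcs-/- mean rests on replicate 4, at 13.5%, without which the difference from the controls fell from 3.49 to 1.08 percentage points. Leaving out DNA-PKcs KD/KD replicate 2 turned the difference of that group to -0.0212. Junctions outside IgH made up 8.75% ± 5.5 (SD, n = 5) in the controls and 39.7% ± 3.9 (SD, n = 2) in DNA-PKcs KD/KD, without overlap (exact permutation p = 0.0476, adjusted 0.167). They made up 17.6% ± 17 (SD, n = 4) in DNA-PKcs-/- (exact permutation p = 0.349, adjusted 0.672) and 27.8% ± 19 (SD, n = 4) in Xrcc4-/- (exact permutation p = 0.0317, adjusted 0.167), both overlapping the controls. Within run 1 the differences were 32.3, 28.7 and 21.2 percentage points, and within run 2 the difference was 4.47 in DNA-PKcs-/-. Here too the DNA-PKcs-/- mean rests on replicate 4, at 43.2%; without it the difference from the controls was 0.260 percentage points. Without Xrcc4-/- replicate 1, at 54.6%, the difference of Xrcc4-/- from the controls fell from 19.0 to 10.1.

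The mutant groups were also compared with each other, to ask whether the DNA-PKcs alleles differ from each other and from loss of Xrcc4. No region's share passed the adjusted threshold. DNA-PKcs-/- minus Xrcc4-/- was -0.937 percentage points for Sμ, 6.93 for Sγ1, 4.65 for Sε, -0.422 for other IgH and -10.2 outside IgH, with exact permutation p from 0.143 to 0.886. DNA-PKcs KD/KD minus DNA-PKcs-/- was -5.67, -9.24, -4.11, -3.12 and 22.1 in the same order, and DNA-PKcs KD/KD minus Xrcc4-/- was -6.60, -2.30, 0.544, -3.54 and 11.9, with exact permutation p of at least 0.267. The ranges overlapped for every one of these shares. Leaving out 1 library moved DNA-PKcs-/- minus Xrcc4-/- across 0 for Sμ (range -4.98 to 2.52) and other IgH (range -2.83 to 1.14), and gave 4.25 to 12.1 for Sγ1, 2.73 to 6.95 for Sε and -18.8 to -1.29 outside IgH. For DNA-PKcs KD/KD minus Xrcc4-/- the sign turned for Sγ1 (range -6.69 to 2.09) and Sε (range -1.50 to 2.59), with ranges of -10.6 to -3.34 for Sμ, -4.84 to -2.27 for other IgH and 7.50 to 20.8 outside IgH. DNA-PKcs KD/KD minus DNA-PKcs-/- ranged from -9.12 to -2.40, -14.5 to -4.85, -6.41 to -2.06, -4.68 to -0.708 and 18.6 to 30.7 in the order above. With 2 libraries against 4, the smallest p possible is 0.0667, so the comparisons of DNA-PKcs KD/KD with either group cannot reach 0.05. Run 1 holds 1 DNA-PKcs-/- library, replicate 4. Within this run DNA-PKcs-/- minus Xrcc4-/- was -9.76, -6.78, -1.56, 7.05 and 11.0 in the order above, opposite in sign to the difference over all runs except for Sμ. DNA-PKcs KD/KD minus DNA-PKcs-/- was 4.69, 6.41, 2.79, -10.4 and -3.54 there, opposite in sign except for other IgH. DNA-PKcs KD/KD minus Xrcc4-/- was -5.07, -0.364, 1.23, -3.30 and 7.50, with the same signs as over all runs.

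Junction structure was examined next, as the share of blunt junctions and of junctions with microhomology of 4 bp or more, since repair without core end-joining factors is known to lengthen microhomology. Over all IgH junctions, 24.9% ± 2.4 (SD, n = 5) were blunt in the controls, 10.2% ± 0.59 (SD, n = 4) in DNA-PKcs-/-, 4.95% ± 0.59 (SD, n = 2) in DNA-PKcs KD/KD and 5.12% ± 0.63 (SD, n = 4) in Xrcc4-/-. Microhomology of 4 bp or more was present in 7.95% ± 1.7 (SD, n = 5), 17.4% ± 2.6 (SD, n = 4), 29.8% ± 0.69 (SD, n = 2) and 24.4% ± 1.4 (SD, n = 4) in the same order. For both measures no library of the 3 groups overlapped the controls, and each exact permutation p was the smallest its design allows (0.00794, 0.0476 and 0.00794). Adjusted over 209 tests these became 0.104, 0.191 and 0.104, so none passed 0.05. In run 1 alone, the blunt share differed from the controls by -14.96, -19.5 and -19.6 percentage points and the microhomology share by 5.43, 20.9 and 15.6. Within run 2 the differences in DNA-PKcs-/- were -12.7 and 11.8. Of the thinnest libraries, DNA-PKcs-/- replicate 4 had 10 blunt junctions of 105, a share of 9.52% (Wilson 95% interval 5.26 to 16.6).

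**Figure D2:**
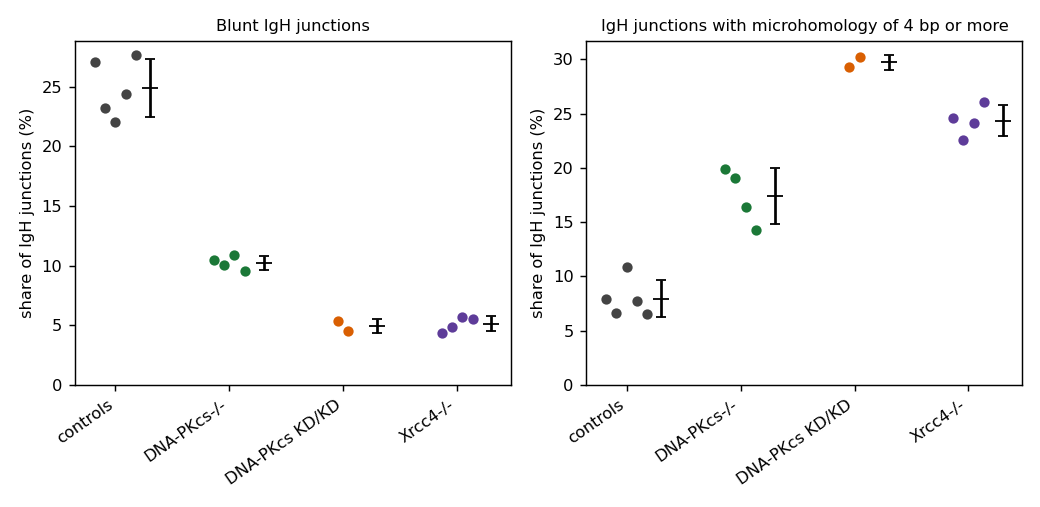
Share of IgH junctions (%) that were blunt and that had microhomology of 4 bp or more, by group. Points are libraries and bars are means with SD; the DNA-PKcs-/- libraries (10.2% blunt on average) lie between the controls (24.9%) and the Xrcc4-/- libraries (5.12%) without overlap.

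DNA-PKcs-/- libraries had more blunt junctions than Xrcc4-/- libraries by 5.11 percentage points and fewer with microhomology of 4 bp or more (difference -6.96), without overlap (exact permutation p = 0.0286 for each, the smallest possible, adjusted 0.191). Within run 1 these differences were 4.61 and -10.2, with 1 DNA-PKcs-/- library. DNA-PKcs KD/KD differed from DNA-PKcs-/- by -5.28 and 12.4 percentage points without overlap (exact permutation p = 0.0667 for each, the smallest possible, adjusted 0.205). Against Xrcc4-/-, DNA-PKcs KD/KD differed by -0.170 percentage points in blunt junctions, with overlap (exact permutation p = 0.733), and by 5.40 in microhomology, without overlap (exact permutation p = 0.0667, adjusted 0.205). Restricted to run 1, the latter differences were 0.0286 and 5.32.

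Junctions within Sμ and to Sε were then taken separately. Within Sμ the blunt share was 23.9% ± 3.6 (SD, n = 5) in the controls, 7.94% ± 4.4 (SD, n = 4) in DNA-PKcs-/-, 4.11% ± 0.32 (SD, n = 2) in DNA-PKcs KD/KD and 5.11% ± 0.79 (SD, n = 4) in Xrcc4-/-, with no overlap with the controls. The share with microhomology of 4 bp or more was 10.4% ± 3.1 (SD, n = 5), 15.9% ± 3.0 (SD, n = 4), 27.5% ± 0.48 (SD, n = 2) and 22.1% ± 0.89 (SD, n = 4), and of these only DNA-PKcs-/- overlapped the controls (exact permutation p = 0.0556, adjusted 0.205). Compared within run 1, the microhomology differences from the controls were 0.516, 15.5 and 10.2 percentage points, and within run 2 the difference was 8.83 in DNA-PKcs-/-. The blunt differences were -9.97, -18.4 and -17.6 within run 1 and -16.7 within run 2. DNA-PKcs-/- lay below Xrcc4-/- in Sμ microhomology by a difference of -6.17 percentage points, without overlap (exact permutation p = 0.0286, adjusted 0.191), and by -9.67 within run 1. The blunt share in Sμ differed by 2.83 between these groups, with overlap (exact permutation p = 0.314), and by 1.31 to 4.78 with 1 library left out.

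At Sε, fewer libraries held the minimum of 20 junctions. The blunt share was 24.8% ± 2.8 (SD, n = 5) in the controls, 18.2% ± 0.21 (SD, n = 2) in DNA-PKcs-/-, 9.88% ± 7.2 (SD, n = 2) in DNA-PKcs KD/KD and 4.87% ± 1.6 (SD, n = 3) in Xrcc4-/-. The share with microhomology of 4 bp or more was 6.40% ± 1.9 (SD, n = 5), 15.6% ± 0.79 (SD, n = 2), 14.6% ± 0.51 (SD, n = 2) and 27.3% ± 2.4 (SD, n = 3). No mutant library overlapped the controls in either measure, and each exact permutation p was the smallest possible (0.0476, 0.0476 and 0.0179; adjusted 0.191, 0.191 and 0.178). Within runs the blunt differences were -5.68 (DNA-PKcs-/-, run 2), -14.4 (DNA-PKcs KD/KD, run 1) and -18.7 (Xrcc4-/-, run 1), and the microhomology differences were 10.2, 7.56 and 19.2. DNA-PKcs-/- exceeded Xrcc4-/- by 13.3 percentage points in blunt junctions and differed by -11.7 in microhomology, without overlap. For these 2 libraries against 3, the exact permutation p of 0.1 is the smallest possible (adjusted 0.258), and no run holds both groups with 20 Sε junctions. The DNA-PKcs KD/KD libraries held 21 and 20 junctions at Sε, so their shares there have wide counting intervals. The blunt difference of this group from the controls was -20.0 without replicate 2 and -9.80 without replicate 1.

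Orientation was compared because deletional joining, which leaves a functional heavy-chain gene, keeps 1 orientation of the prey. Of Sγ1 junctions, 88.1% ± 2.9 (SD, n = 6) were deletional in the controls, 85.7% ± 6.5 (SD, n = 4) in DNA-PKcs-/-, 68.7% ± 6.8 (SD, n = 2) in DNA-PKcs KD/KD and 65.2% ± 2.9 (SD, n = 4) in Xrcc4-/-. The last 2 groups did not overlap the controls, with the smallest exact permutation p possible for each (0.0357, adjusted 0.125; 0.00476, adjusted 0.1), whereas DNA-PKcs-/- overlapped them (0.486, adjusted 0.659). The share in DNA-PKcs-/- exceeded that in Xrcc4-/- by 20.5 percentage points without overlap (exact permutation p = 0.0286, adjusted 0.125), and by 11.8 within run 1. Among libraries of run 1, the differences from the controls were -10.9, -18.4 and -22.7. Within run 2 the difference was 0.342 in DNA-PKcs-/-, and within run 3 it was -23.8 in Xrcc4-/-. Leaving out DNA-PKcs-/- replicate 4 turned that group's difference from the controls from -2.48 to 0.673. In the authors' pools the deletional share at Sγ1 was 93.2% in wild type, 92.0% in DNA-PKcs-/-, 85.1% in DNA-PKcs KD/KD and 79.9% in Xrcc4-/-.

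At Sε, 94.0% ± 2.5 (SD, n = 5) of control junctions were deletional, as were 93.7% ± 2.8 (SD, n = 2) in DNA-PKcs-/- (exact permutation p = 0.857) and 90.4% ± 6.6 (SD, n = 2) in DNA-PKcs KD/KD (exact permutation p = 0.286), both overlapping the controls. The share was 73.7% ± 5.7 (SD, n = 3) in Xrcc4-/- without overlap (exact permutation p = 0.0179, adjusted 0.125). DNA-PKcs-/- exceeded Xrcc4-/- by 19.9 percentage points (exact permutation p = 0.1, the smallest possible). Within Sμ, 75.0% ± 4.8 (SD, n = 6) were deletional in the controls, 64.4% ± 6.4 (SD, n = 4) in DNA-PKcs-/- (exact permutation p = 0.0238, adjusted 0.125, overlapping), 60.5% ± 3.7 (SD, n = 2) in DNA-PKcs KD/KD (exact permutation p = 0.0357, adjusted 0.125, not overlapping) and 68.8% ± 4.2 (SD, n = 4) in Xrcc4-/- (exact permutation p = 0.0762, adjusted 0.2, overlapping). In run 1 alone, the Sε differences were -2.52 in DNA-PKcs KD/KD and -19.8 in Xrcc4-/-, and within run 2 the difference was -1.36 in DNA-PKcs-/-. The Sμ differences within run 1 were 0.387, -12.3 and -3.49, and they were -12.1 in DNA-PKcs-/- within run 2 and -14.5 in Xrcc4-/- within run 3. The difference of -4.47 between DNA-PKcs-/- and Xrcc4-/- in Sμ had an exact permutation p of 0.314, with overlap. It was 3.88 within run 1 and ranged from -7.41 to -2.45 with 1 library left out. None of the 21 orientation tests passed after adjustment. The DNA-PKcs-/- difference at Sε, -0.292, turned to values of at most 1.66 when wild-type replicate 1, 1 of the further control libraries or DNA-PKcs-/- replicate 1 was left out, and that of DNA-PKcs KD/KD to 1.03 without replicate 1.

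Positions along the switch regions were compared by the share of a library's junctions outside the interval that holds the central 95% of the controls' junctions. In coordinates of mm9 with the switch region replaced by the 129 sequence, these intervals are 114664864 to 114670606 on chromosome 12 for Sμ, 114566531 to 114578792 for Sγ1 and 114512459 to 114515573 for Sε. In Sμ the share outside rose from 5.55% ± 1.1 (SD, n = 6) in the controls to 15.5% ± 5.6 (SD, n = 4) in DNA-PKcs-/- and 28.7% ± 1.9 (SD, n = 4) in Xrcc4-/-. In Sγ1 it rose from 5.64% ± 1.6 (SD, n = 6) to 21.7% ± 7.8 (SD, n = 4) and 33.6% ± 3.5 (SD, n = 4). Each of these 4 differences held in 4 of 4 libraries and had an exact permutation p of 0.00476, the smallest possible, and an adjusted p of 0.05 over 42 tests. The adjusted value lies exactly at the threshold, and leaving out any 1 of the 10 libraries of a comparison took its adjusted p above it. With sequencing run as a block, the differences were 7.01 (DNA-PKcs-/-, Sμ), 23.9 (Xrcc4-/-, Sμ), 15.4 (DNA-PKcs-/-, Sγ1) and 26.8 percentage points (Xrcc4-/-, Sγ1). The exact permutation p was then 0.0625 for both DNA-PKcs-/- differences and 0.05 for both Xrcc4-/- differences, each the smallest the blocked design allows. None of them stayed past the adjusted threshold. Fewer libraries or permutations raise the smallest p possible, so these losses do not show that run or 1 library accounts for the differences. Without 1 library the differences ranged from 8.77 to 12.7 (DNA-PKcs-/-, Sμ), 22.5 to 24.0 (Xrcc4-/-, Sμ), 12.2 to 17.6 (DNA-PKcs-/-, Sγ1) and 26.9 to 29.0 percentage points (Xrcc4-/-, Sγ1).

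In DNA-PKcs KD/KD the share outside was 21.2% ± 0.0083 (SD, n = 2) in Sμ and 30.01% ± 5.1 (SD, n = 2) in Sγ1, above every control (exact permutation p = 0.0357 for each, the smallest possible, adjusted 0.15). Within run 1 the Sμ differences were 1.51 in DNA-PKcs-/-, 15.5 in DNA-PKcs KD/KD and 23.1 in Xrcc4-/-. They were 12.5 in DNA-PKcs-/- within run 2 and 24.6 in Xrcc4-/- within run 3. For Sγ1 they were 12.0, 23.0 and 27.6 within run 1, 18.7 in DNA-PKcs-/- within run 2 and 26.0 in Xrcc4-/- within run 3. DNA-PKcs-/- minus Xrcc4-/- was -13.2 in Sμ without overlap (exact permutation p = 0.0286, adjusted 0.15) and -11.9 in Sγ1 (exact permutation p = 0.0857, adjusted 0.257). In Sμ the junctions outside lay mostly below the interval, on the side towards the constant regions: 3.43% ± 1.4 (SD, n = 6) of junctions in the controls, 14.6% ± 5.0 (SD, n = 4) in DNA-PKcs-/-, 20.7% ± 0.64 (SD, n = 2) in DNA-PKcs KD/KD and 27.8% ± 2.5 (SD, n = 4) in Xrcc4-/-.

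The Sγ1 positions have a further limit. Junctions listed in the authors' pools but in no library lay inside the controls' interval in 99.2% of cases for DNA-PKcs KD/KD and 99.5% for Xrcc4-/-, against 69.4% and 68.8% of junctions in both lists. In the pools the share outside was therefore 10.6% (60 of 565) for DNA-PKcs KD/KD and 11.5% (608 of 5271) for Xrcc4-/-. The interval itself comes from control libraries, and no control pool listing Sγ1 junctions was analysed here, so the Sγ1 differences apply to the library lists. At Sε the share outside was 5.96% ± 2.4 (SD, n = 5) in the controls, 11.1% ± 0.26 (SD, n = 2) in DNA-PKcs-/-, 9.76% ± 0.34 (SD, n = 2) in DNA-PKcs KD/KD and 24.2% ± 2.5 (SD, n = 3) in Xrcc4-/-, with exact permutation p of 0.0476, 0.143 and 0.0179 (adjusted 0.182, 0.3 and 0.15). Within runs those differences were 4.34 (run 2), 3.50 and 17.2 (run 1). DNA-PKcs-/- minus Xrcc4-/- at Sε was -13.1 (exact permutation p = 0.1, the smallest possible).

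The other 21 tests of position compared the median position, counted in bp from the end of the region with the lowest coordinate, and none passed after adjustment. In Sμ the median was 6863 ± 258 (SD, n = 6) in the controls, 7042 ± 163 (SD, n = 4) in DNA-PKcs-/-, 6762 ± 267 (SD, n = 2) in DNA-PKcs KD/KD and 6326 ± 348 (SD, n = 4) in Xrcc4-/-. The differences of 179, -101 and -537 bp had exact permutation p of 0.252, 0.786 and 0.0286 (adjusted 0.431, 0.943 and 0.15), so the median in DNA-PKcs-/- did not move to the side of the junctions outside the interval. They were 406, -44.0 and -475 within run 1, 145 in DNA-PKcs-/- within run 2 and -576 in Xrcc4-/- within run 3. Between DNA-PKcs-/- and Xrcc4-/- the difference was 716 bp without overlap (exact permutation p = 0.0286, adjusted 0.15) and 881 within run 1. In Sγ1 the differences from the controls were 949, 192 and 3473 bp, with exact permutation p of 0.681, 0.929 and 0.0571, and at Sε they were -172, -17.7 and -203 bp, with 0.143, 0.952 and 0.125. Those in Sγ1 within run 1 were 7237, 362 and 3190. The difference between DNA-PKcs-/- and Xrcc4-/- was -2524 bp in Sγ1 (exact permutation p = 0.314) but 4047 within run 1, and 31.7 at Sε (exact permutation p = 0.9). With 1 library left out the sign turned for DNA-PKcs KD/KD in Sμ (range -289 to 87.8), Sγ1 (-155 to 632) and Sε (-201 to 165), for DNA-PKcs-/- in Sγ1 (-1091 to 1688) and for DNA-PKcs-/- minus Xrcc4-/- at Sε (-47.5 to 137). It did not turn for DNA-PKcs-/- in Sμ (83.2 to 232) and Sε (-194 to -124), for Xrcc4-/- in Sμ (-648 to -378), Sγ1 (2354 to 4276) and Sε (-308 to -124), and for DNA-PKcs-/- minus Xrcc4-/- in Sμ (558 to 827) and Sγ1 (-4564 to -1405).

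**Figure D3:**
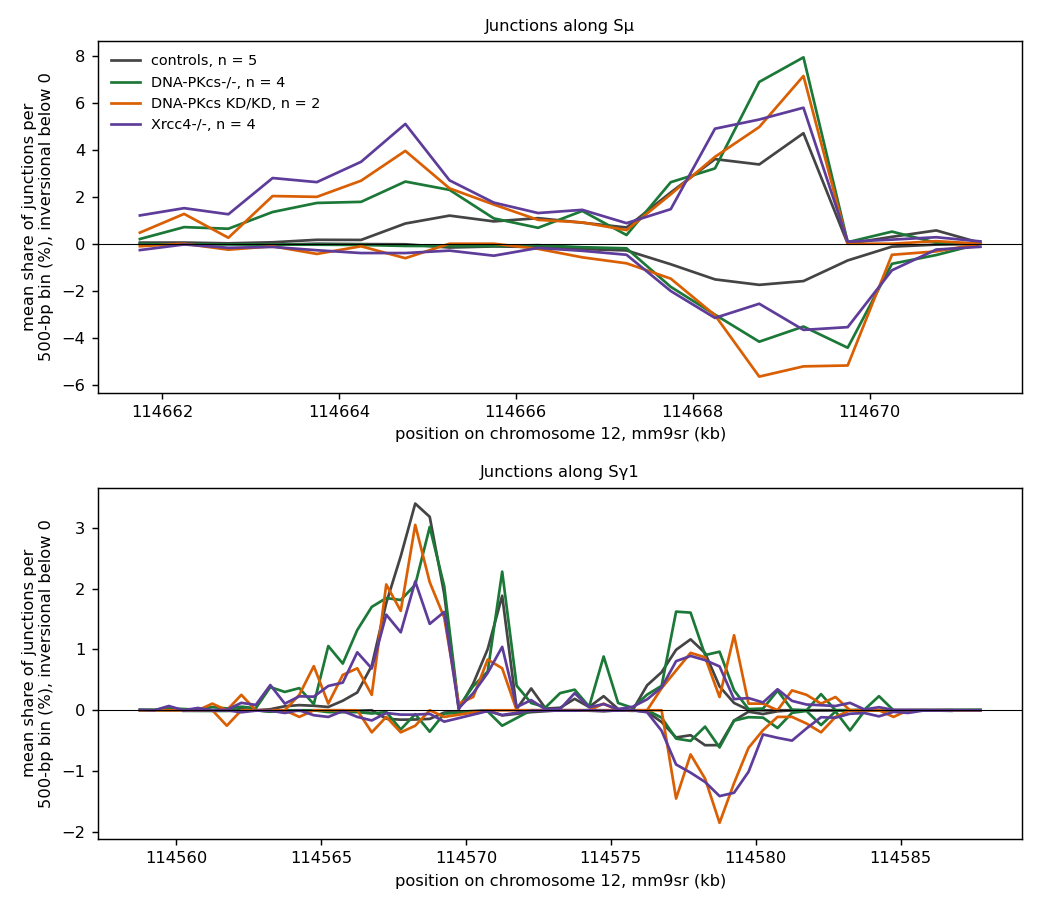
Mean share of a library's Sμ, Sγ1 and Sε junctions (%) per bin of 500 bp along Sμ and Sγ1 (chromosome 12 coordinates of mm9 with the 129 switch region), for the controls (n = 5), DNA-PKcs-/- (n = 4), DNA-PKcs KD/KD (n = 2) and Xrcc4-/- (n = 4). Deletional junctions are drawn above 0 and inversional ones below; in Sμ the mutant groups show junctions at low coordinates, such as the deletional bin from 114663001, where the controls averaged 0.0612% and Xrcc4-/- 2.80%.

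To find where along the switch regions junctions differed, junctions in 88 bins of 500 bp and orientation were tested with edgeR over 15 libraries. Past an adjusted p of 0.05, DNA-PKcs-/- had 23 bins higher and 12 lower than the controls, DNA-PKcs KD/KD 15 higher and 7 lower, and Xrcc4-/- 38 higher and 10 lower. The numbers of bins with an unadjusted p under 0.05 were 40, 31 and 53. In all 3 comparisons, all bins past the threshold in Sε were lower (11, 7 and 8 bins), and those in Sμ and Sγ1 were higher except for 1 deletional Sμ bin in DNA-PKcs-/- and in Xrcc4-/- and 1 deletional Sγ1 bin in Xrcc4-/-. Because counts are relative to the library's junctions in the 3 regions, fewer Sε junctions raise the other bins. With TMM normalization in place of library totals, 19, 12 and 25 bins were higher. With DESeq2 in place of edgeR, 7, 8 and 14 bins were higher and 10, 7 and 13 lower. With sequencing run as a covariate, the bins higher were 4, 11 and 22 and those lower 8, 7 and 11, and 12 of the 35 bins of DNA-PKcs-/- remained past the threshold. Leaving out DNA-PKcs KD/KD replicate 2 left 5 bins higher and 4 lower in that group, and leaving out Xrcc4-/- replicate 3 left 22 higher and 11 lower in Xrcc4-/-. Leaving out DNA-PKcs-/- replicate 2 left 18 bins higher and 8 lower in DNA-PKcs-/-.

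Of the bins with the largest rises, the deletional Sμ bin from 114663001 to 114663500 was named in every comparison. It held 0.0612% ± 0.088 (SD, n = 5) of control junctions, 1.35% ± 1.1 (SD, n = 4) in DNA-PKcs-/-, 2.03% ± 0.72 (SD, n = 2) in DNA-PKcs KD/KD and 2.80% ± 0.25 (SD, n = 4) in Xrcc4-/-. The counts were 2 of 5940 in the controls against 71 of 5034, 12 of 656 and 161 of 5878, which gave pooled ratios of 41.9 (95% interval 11.2 to 353), 54.3 (12.1 to 500) and 81.3 (22.2 to 677). The edgeR adjusted p-values were 1.25e-10, 6.69e-07 and 5.12e-19, and with run as a covariate 0.00361, 0.000151 and 1.1e-09. In DNA-PKcs-/- the 5 largest rises were the deletional Sμ bins that start at 114662001, 114662501, 114663001, 114663501 and 114664001, with pooled ratios from 11.3 to 48.4. Of these, only the bin from 114663501 showed no overlap between DNA-PKcs-/- and control libraries. Replicates 1 and 2, both of run 2, held 2209 and 2637 of the group's 5034 junctions and weigh most in its pooled ratios. With run as a covariate only those that start at 114663001 and 114663501 of these 5 stayed past the threshold. In Xrcc4-/- the others were the deletional Sμ bins from 114662001 (ratio 42.4, interval 11.4 to 356) and 114662501 (72.8, 12.6 to 2913) and inversional Sγ1 bins from 114579501 (57.6, 9.93 to 2315) and 114581001. The last held 25 junctions in Xrcc4-/- and 0 in the controls, so it was at least 8.42-fold higher, with 3 counts over the control group as the floor.

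In DNA-PKcs KD/KD the other rises rest on few junctions. The deletional Sμ bin from 114662001 held 9 of 656 junctions (ratio 40.7, interval 8.43 to 388). The inversional Sμ bin from 114663501 held 4, all in replicate 2, and was at least 12.1-fold higher than the controls, which had 0. Without that library the bin held too few junctions to be tested, so this rise rests on 1 library. The inversional Sγ1 bin from 114579501 held 3 junctions against 1 in the controls, and that from 114581501 held 2 against 0, too few for a fold. The latter's adjusted p of 0.0468 from edgeR rose to between 0.0501 and 0.106 when any 1 of the 5 control libraries was left out. The bin from 114579501 lost its call without 1 of the further control libraries (edgeR adjusted p = 0.0743) or DNA-PKcs KD/KD replicate 1 (0.279), and the deletional Sμ bin from 114662001 without DNA-PKcs KD/KD replicate 2 (0.0572).

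The largest falls were in Sε. The deletional bin from 114514001 to 114514500 held 9.44% ± 1.5 (SD, n = 5) of control junctions, 1.87% ± 1.5 (SD, n = 4) in DNA-PKcs-/-, 0.798% ± 0.41 (SD, n = 2) in DNA-PKcs KD/KD and 0.598% ± 0.42 (SD, n = 4) in Xrcc4-/-, with log2 fold changes of -2.33, -3.39 and -3.65. No mutant library overlapped the controls there, and the edgeR adjusted p-values were 1.11e-10, 1.38e-07 and 1.28e-23. In DNA-PKcs-/- the other falls were the deletional Sε bin from 114514501 (log2 fold change -2.45), the inversional Sε bins from 114515001 (7 junctions against 43) and 114515501 (0 against 22, at least 6.21-fold lower), and a deletional Sμ bin from 114670501 (4 against 36). With run as a covariate neither inversional bin stayed past the threshold, and that from 114515001 also did not without DNA-PKcs-/- replicate 2 (edgeR adjusted p = 0.0513). In DNA-PKcs KD/KD the others were the deletional Sε bins from 114513001, 114513501 and 114515501, with 2, 3 and 1 junctions against 281, 537 and 88, which are pooled ratios of 0.0644 (interval 0.00777 to 0.235), 0.0506 (0.0104 to 0.149) and 0.103 (0.00258 to 0.588). In each of these bins the DNA-PKcs KD/KD junctions came from 1 library only. The mean shares of the first 2 were 0.218% ± 0.31 and 0.761% ± 1.1 (SD, n = 2), so the sizes of these falls are uncertain. In the same group the inversional bin from 114515001 held 0 against 43, at least 1.58-fold lower. The bins from 114515001 and 114515501 lost their calls without either DNA-PKcs KD/KD library (edgeR adjusted p 0.0668 and 0.379 for the first and 0.087 and 0.135 for the second, without replicate 1 and 2). In Xrcc4-/- the others were the deletional Sε bins from 114513501, 114514501, 114515001 and 114515501, with log2 fold changes from -3.88 to -3.12.

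**Figure D4:**
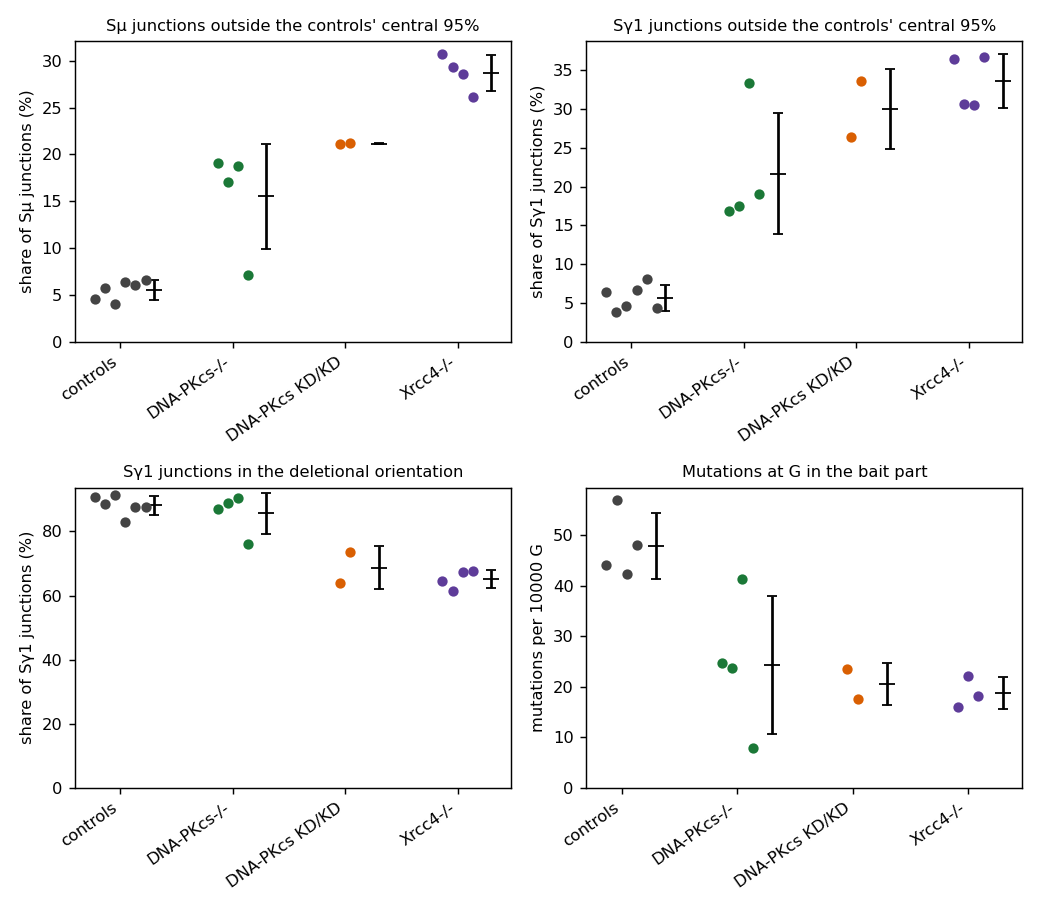
Share of Sμ and of Sγ1 junctions outside the controls' central 95% interval (%), share of Sγ1 junctions in the deletional orientation (%) and mutations per 10000 G in the bait, by group. Points are libraries and bars are means with SD; the deletional share at Sγ1 averaged 88.1% in the controls, 85.7% in DNA-PKcs-/-, 68.7% in DNA-PKcs KD/KD and 65.2% in Xrcc4-/-.

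Mutations at G in the 5′ Sμ bait part were counted because the design of the series names them. Where the mutation sheets cover IgH junctions, there were 47.9 ± 6.5 (SD, n = 4) mutations per 10000 G in the controls, 24.4 ± 14 (SD, n = 4) in DNA-PKcs-/-, 20.6 ± 4.2 (SD, n = 2) in DNA-PKcs KD/KD and 18.9 ± 3.1 (SD, n = 3) in Xrcc4-/-. No mutant library overlapped the controls, with the smallest exact permutation p possible in each comparison (0.0286, 0.0667 and 0.0286; adjusted over 42 tests 0.6, 0.933 and 0.6). Restricted to run 1, the differences were -40.0, -27.3 and -29.0. Counts were low in the small libraries, with 5 mutations in 1211 G in DNA-PKcs-/- replicate 3 and 1 in 1275 in replicate 4. Replicate 3, at 41.3 per 10000 G, lay just below the controls, which ran from 42.4 to 57.0. Its Wilson interval of 17.6 to 96.3 covers every control value. The lack of overlap in DNA-PKcs-/- is therefore within the counting error of this library. DNA-PKcs-/- minus Xrcc4-/- was 5.58 (exact permutation p = 0.571), and leaving out DNA-PKcs-/- replicate 3 turned it to -0.0363. Within run 1, with 1 DNA-PKcs-/- library, it was -11.0.

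The other measures of bait mutations separated the groups less. Over all bases there were 29.3 ± 10 (SD, n = 4) mutations per 10000 in the controls, 22.6 ± 5.1 (SD, n = 4) in DNA-PKcs-/-, 19.4 ± 12 (SD, n = 2) in DNA-PKcs KD/KD and 16.0 ± 3.5 (SD, n = 3) in Xrcc4-/-, and of these only Xrcc4-/- did not overlap the controls (exact permutation p = 0.314, 0.333 and 0.114). The share of mutations that were at G was 45.9% ± 9.6 (SD, n = 4) in the controls, 33.0% ± 27 (SD, n = 4), 31.7% ± 13 (SD, n = 2) and 31.0% ± 4.5 (SD, n = 3), again with overlap except in Xrcc4-/- (exact permutation p = 0.457, 0.267 and 0.114). In DNA-PKcs-/- this share ran from 1 of 13 mutations (7.69%) in replicate 4 to 5 of 7 (71.4%) in replicate 3. Differences from the controls per 10000 were -0.890, -5.01 and -6.92 at C, -2.14, -4.13 and -9.82 at A and 3.97, -2.41 and -4.02 at T, all with overlap and exact permutation p of at least 0.4. Within run 1 the single DNA-PKcs-/- library differed from the controls by -1.52 over all bases, 3.15 at C, 19.7 at A, 15.4 at T and -40.5 percentage points in the share at G. The values of DNA-PKcs KD/KD there were -8.77, -3.39, -3.13, -0.180 and -16.4, and those of Xrcc4-/- were -12.1, -5.30, -8.82, -1.79 and -17.2.

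With 1 library left out, the differences over all bases were -9.62 to -2.43 in DNA-PKcs-/-, -18.1 to -1.72 in DNA-PKcs KD/KD and -16.2 to -9.02 in Xrcc4-/-, and those in the share at G were -25.8 to -4.51, -23.2 to -5.14 and -18.1 to -12.0. The sign turned at C (-4.24 to 5.35 in DNA-PKcs-/-, -19.6 to 9.55 in DNA-PKcs KD/KD) and at A (-9.08 to 4.95 and -13.1 to 4.80). Ranges in Xrcc4-/- were -10.8 to -2.64 at C, -14.4 to -2.73 at A and -8.05 to -0.168 at T, and at T they were 0.894 to 9.69 in DNA-PKcs-/- and -3.92 to -0.180 in DNA-PKcs KD/KD. Between DNA-PKcs-/- and Xrcc4-/- the differences were 6.58 over all bases, 6.03 at C, 7.68 at A, 7.99 at T and 1.95 percentage points in the share at G, with overlap and exact permutation p from 0.143 to 1. Within run 1 they were 10.6, 8.45, 28.5, 17.2 and -23.3, and with 1 library left out 5.15 to 9.05, 2.68 to 12.3, 0.739 to 12.3, 4.14 to 13.7 and -10.9 to 10.4. None of the 42 tests passed after adjustment.

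The design also names translocations with long microhomology in DNA-PKcs KD/KD cells. Of junctions outside IgH, 11.5% ± 5.7 (SD, n = 5) had microhomology over 10 bp in the controls, 4.31% ± 4.6 (SD, n = 3) in DNA-PKcs-/-, 16.1% ± 23 (SD, n = 2) in DNA-PKcs KD/KD and 15.2% ± 14 (SD, n = 3) in Xrcc4-/-. The exact permutation p-values against the controls were 0.125, 0.667 and 0.679, and all 3 adjusted values were 0.969. No minimum of junctions applied to this measure. DNA-PKcs-/- replicate 3 entered with 0 of 15 junctions, which allows up to 20% by 3 counts, against 17 of 186 in replicate 1 and 3 of 79 in replicate 4. The DNA-PKcs KD/KD libraries differed from each other: replicate 2 had 114 of 353 (32.3%, Wilson 95% interval 27.6 to 37.3), and replicate 1 had 0 of 117, which allows a share of up to 2.56% by 3 counts of the total (upper Wilson bound 3.18%). The list of replicate 1 holds microhomology of up to 10 bp, and a length limit in the making of that list cannot be ruled out. Without replicate 2 the difference from the controls turned to -11.5 percentage points, and without Xrcc4-/- replicate 4, which had 110 of 347 (31.7%, 27.0 to 36.8), that of Xrcc4-/- turned to -4.53. Among libraries of run 1, the differences were -5.69, 6.66 and 5.75, and within run 2 the difference was -12.8 in DNA-PKcs-/-.

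Outside IgH, 13 libraries listed 2093 junctions, which fell in 1180 windows of 1 Mb, 779 of them with junctions in 1 library only. The wild-type libraries contributed 212 of them, DNA-PKcs-/- 280, DNA-PKcs KD/KD 470 and Xrcc4-/- 849. The 5 windows with junctions in the most libraries were on chromosome 12 from 70000001 (34 junctions in 10 libraries), chromosome 7 from 132000001 (37 in 9), chromosome 12 from 114000001 (18 in 9), chromosome 12 from 113000001 (14 in 9) and chromosome 9 from 107000001 (14 in 8). In the first window 21 junctions lay between 70293690 and 70303565, 10 of them in exons and 5 in introns of 1110034A24Rik or 9330151L19Rik. In the second, 24 lay between 132695668 and 132704921, 23 of them in introns of Il4ra. The densest 10 kb of the others held 6 junctions, 4 of them in introns of Gpr132, 3 junctions in introns of Inf2, and 7 junctions, 5 of them in exons of Cish or Gm17041. The chromosome 12 window from 114000001 also contains the switch regions, and that from 113000001 adjoins it. Junctions in these windows therefore lie near the bait on its own chromosome. Of the loci chosen in advance, 13 had a junction within 10 kb: Igk had 36 in 9 libraries, Il4ra 26 in 8, Pim1 12 in 4 (10 of them in Xrcc4-/-), Bcl6 7, Ly6e 7, Pax5 6, Cd83 3, Pvt1 2 and Igl 2. The Hist1 cluster, Cd79b, Mir142 and Nsmce1 had 1 each. Loci with 0 included Myc, Bcl2, Rhoh, Gas5, Ebf1, Prkdc and Xrcc4, and junctions at the last 2 of these cannot check the genotypes. These counts were not compared between groups, since most loci hold too few junctions.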

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

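The tests of long microhomology reported in this part were chosen only after the result was seen.

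In 36 groups of 4 to 10 libraries, 3 values lay far from the others of their group by the size of the gap, and chance gives about 1 in 20. All 3 belong to the smallest libraries of DNA-PKcs-/-. Replicate 4 had 7.14% of its Sμ junctions outside the controls' central interval (4 of 56, Wilson 95% interval 2.81 to 17.0), against 17.1 to 19.1% in the others. Replicate 3 had 33.3% of its Sγ1 junctions outside (14 of 42, 21.0 to 48.4), against 16.9 to 19.0%. Replicate 4 also had 43.2% of its junctions outside IgH (80 of 185, 36.3 to 50.4), against 6.83 to 12.7%. Replicate 4 is the only DNA-PKcs-/- library of run 1, so the library, its depth and its run cannot be separated. No explanation was tested for these values.

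Insertions over 30 bp were left out of the main values. In run 1, where such insertions are listed, the Wilson 95% interval of their share lay above the highest control share (wild-type replicate 4, 6.45%, interval 4.87 to 8.50) in 3 libraries. These were Xrcc4-/- replicate 1 at 10.6% (8.49 to 13.1), Xrcc4-/- replicate 4 at 10.4% (8.98 to 12.1) and DNA-PKcs KD/KD replicate 2 at 23.0% (20.6 to 25.6). The share in DNA-PKcs KD/KD replicate 1 was 6.88% (4.66 to 10.0). DNA-PKcs-/- replicate 4, whose list holds none, was left out.

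DNA-PKcs KD/KD replicate 2 also has the largest share of long microhomology outside IgH, 32.3% of 353 junctions, followed by Xrcc4-/- replicate 4 with 31.7% of 347. The kinase-dead genotype as the sole cause is argued against by replicate 1 of the same genotype, where 0 of 117 junctions had microhomology over 10 bp (upper Wilson bound 3.18%), below every control. A limit on length in the list of replicate 1 cannot be ruled out, but the libraries also differ below such a limit. Microhomology of 6 to 10 bp was present in 7 junctions of replicate 1 (5.98%, 2.93 to 11.8) and in 143 of replicate 2 (40.5%, 35.5 to 45.7). Libraries of 1 genotype differ in this share elsewhere in run 1 as well, with 4.29% (1.47 to 11.9) and 24.4% (17.5 to 32.8) in wild-type replicates 1 and 4 and 6.98% (4.04 to 11.8) and 25.1% (20.8 to 29.9) in Xrcc4-/- replicates 2 and 4. A property of single libraries that raises both long insertions and long microhomology stays open. Sequencing adapter was found in part of the insertions over 30 bp outside IgH (58 of 238 in DNA-PKcs KD/KD replicate 2, 4 of 22 in replicate 1, 31 of 145 in Xrcc4-/- replicate 4 and 11 of 30 in wild-type replicate 1), a technical source that was not tested further. Over the 8 libraries of run 1 with such lists, the Spearman correlation of the shares was 0.571 (exact permutation p = 0.151) and Pearson's r was 0.734 (exact permutation p = 0.0387). Without DNA-PKcs KD/KD replicates 1 and 2, the farthest from the median, r was 0.363, so the relation rests on those samples, and 8 libraries are too few to decide. The use of unpurified cells is shared by both replicates and was not tested, and a contribution of the genotype together with another factor stays open as well.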

How the results depend on the processing

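Alternatives chosen only after the result was seen are sequencing run as a block or covariate, the authors' pooled counts, insertions over 30 bp included, outside region usage and bins, the omission of libraries under 500 junctions and, for long microhomology, the replicate block.

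The 130 results had 2120 alternatives. Of these, 2004 kept their side of the threshold, stayed within 1.5 times the count or stayed within the spread. A further 71 fell short of the threshold or of 1.5 times the count, and 13 passed it. Another 32 values without a test moved by more than the spread, and 0 calls reversed. Among the results tested by permutation, only the 4 position differences were called, so for the others keeping the side means staying uncalled. Some of these comparisons had too few libraries to pass at all. The count of kept results therefore does not measure how stable the uncalled differences are. A turned sign of a difference not called did not count as a change here. The sign turned in 91 alternatives of 37 results.

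The 4 position calls lie at the threshold, with adjusted p from 0.05 to 0.422 over their alternatives, and their differences kept their direction in every alternative run. The values follow in the order Sμ in DNA-PKcs-/-, Sμ in Xrcc4-/-, Sγ1 in DNA-PKcs-/-, Sγ1 in Xrcc4-/-. They were 10.3, 23.5, 16.3 and 28.2 percentage points with wild type alone as controls (adjusted p 0.171), 12.5, 23.1, 11.5 and 28.0 without libraries under 500 junctions (0.25, 0.1, 0.25 and 0.1), and 8.87, 23.1, 11.5 and 28.0 with a minimum of 50 junctions (0.143, 0.0857, 0.156 and 0.0857). With the replicate block they were 10.1, 23.2, 16.0 and 28.0 (0.292), and with the run block 7.01, 23.9, 15.4 and 26.8 (0.422). Leaving out each library gave 8.77 to 12.7, 22.5 to 24.0, 12.2 to 17.6 and 26.9 to 29.0. Each loss of a call comes with fewer libraries or permutations, or fewer libraries in another test of the family, which raises the smallest adjusted p possible.

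As shares of IgH junctions, 7 differences from the controls passed (adjusted p 0.0397, with 0.0397 to 0.857 over the alternatives of these results). These were Sμ in DNA-PKcs-/- (21.97) and Xrcc4-/- (30.7), Sε in DNA-PKcs-/- (-33.8) and Xrcc4-/- (-38.6), other IgH in Xrcc4-/- (6.03), and Sε over Sε plus Sγ1 in DNA-PKcs-/- (-40.9) and Xrcc4-/- (-47.7). The ratio has the same value and exact permutation p under both denominators, so its call comes from the other tests of the family: the shares outside IgH drop out and other IgH in Xrcc4-/- reaches the smallest p possible. With junctions pooled over libraries, the Sμ share in DNA-PKcs-/- differed by 21.6, IgH microhomology of 4 bp or more by 11.9, and Sμ microhomology between DNA-PKcs-/- and Xrcc4-/- by -3.88; the cause was not tested.

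The authors' pooled counts hold more Sγ1 junctions than the libraries, and 1.18 to 1.26 times as many Sμ junctions in the mutant groups. With them, differences from the controls in the order DNA-PKcs-/-, DNA-PKcs KD/KD, Xrcc4-/- were -20.5, -22.8 and -22.0 for the Sε share, -25.4, -26.1 and -25.6 for Sε over Sε plus Sγ1, and 13.3, 24.6 and 19.5 for IgH microhomology. In DNA-PKcs KD/KD the pooled differences were 15.5 for Sμ, -17.8 for Sγ1, -0.250 for other IgH, 25.2 outside IgH and -7.50 for the deletional share at Sγ1. Those in Xrcc4-/- were -9.34 for the Sγ1 share, -11.4 and -12.7 for the deletional share in Sμ and Sγ1, and -22.9 and 23.7 for blunt junctions and microhomology at Sε. Sμ microhomology in DNA-PKcs-/- differed by 10.2. DNA-PKcs-/- minus Xrcc4-/- was 16.9 for the Sγ1 share, 0.159 for Sε over Sε plus Sγ1, 12.1 for the deletional share at Sγ1, 6.24 for IgH blunt junctions, -3.64 for Sμ microhomology, and 14.5 and -14.4 for blunt junctions and microhomology at Sε. DNA-PKcs KD/KD minus DNA-PKcs-/- was 3.97 for Sμ and -25.3 for Sγ1. The pools carry no replicates, and the wild-type pool exceeds the wild-type libraries with counts in Sε as well (4142 junctions against 823). Apart from the added Sγ1 junctions and this mismatch of wild-type libraries, the cause was not tested.

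Of the bin counts, bins of 200 bp gave 38 higher and 20 lower in DNA-PKcs-/-, 23 and 12 in DNA-PKcs KD/KD, and 19 lower in Xrcc4-/-, over 149 bins in place of 88. Bins of 1000 bp gave 3 lower in DNA-PKcs KD/KD, over 58 bins. DESeq2 gave 7, 8 and 14 higher in DNA-PKcs-/-, DNA-PKcs KD/KD (26 bins without an adjusted p) and Xrcc4-/-, and run as a covariate gave 4 higher in DNA-PKcs-/- and 22 in Xrcc4-/-. In Xrcc4-/-, TMM gave 25 higher, wild type alone 23 and no filter 59, over 178 bins; apart from the numbers of bins, the cause was not tested. Leaving out each library gave 5 to 16 higher and 4 to 7 lower in DNA-PKcs KD/KD, lowest without replicate 2, and 22 to 39 higher in Xrcc4-/-, lowest without replicate 3 (77 bins tested). With 1 library left in DNA-PKcs KD/KD, edgeR assumes that it varies like the other groups. No bin called in both turned direction under any alternative. Of 457 alternatives of the 30 named bins, 427 kept the call, 30 fell short and 0 reversed.

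The replicate numbers do not pair the libraries: of 24 same-numbered pairs, 6 had a correlation over 0.1 (range -0.717 to 0.326), and 0 of 15 libraries correlated best with their own number, so the replicate block serves as an alternative only. Low depth limits DNA-PKcs-/- replicates 3 and 4, the Sε values of DNA-PKcs KD/KD and Xrcc4-/- replicate 1 at Sε, where it held 7 junctions.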

Other observations

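Chosen only after the result was seen were the tests of further sequencing, of position as the whole of the orientation difference, of sequencing run and of the orientation in the pools.

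The authors' pooled lists hold 3.08 times as many Sγ1 junctions as the libraries of DNA-PKcs KD/KD, 3.70 times for DNA-PKcs-/- and 2.83 times for Xrcc4-/-. For Sμ the ratios in the same order were 1.26, 1.18 and 1.19, a smaller gain whose cause was not tested. Further sequencing of the same cells as the source of the Sγ1 gain is argued against. The ratio for Sε was at most 1.03 while that for Sγ1 was at least 2.83 over these 3 groups. A candidate explanation is that reads that fit several places in the Sγ1 repeats were left out of the library lists. Junctions were aligned to chromosome 12 of NCBIM37, which lacks the 129 switch sequence. In DNA-PKcs KD/KD, 312 of the 379 junctions found in the pool only aligned, and 163 of the 186 also in a library. Of the aligned ones, 50% (Wilson 95% interval 44.5 to 55.5) and 7.98% (4.72 to 13.2) had mapping quality 0, a difference of 42.0 percentage points. In Xrcc4-/-, 3130 of 3383 and 1800 of 1888 aligned. Of these, 44.8% (43.0 to 46.5) and 7.94% (6.78 to 9.29) had mapping quality 0, a difference of 36.8. Both fit that explanation, which does not account for the pool-only reads that mapped to 1 place. Junctions that did not align were not assessed.

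Xrcc4-/- libraries had fewer deletional Sγ1 junctions than the controls. Sequencing run as the cause is argued against by differences of -22.7 percentage points within run 1 and -23.8 within run 3. A different distribution of positions within Sγ1 may account for part. After windows of 2 kb were weighted by the controls' distribution, the difference was -10.3, against -22.9 without weights, with means of 77.0% ± 4.3 (SD, n = 4) and 87.3% ± 3.2 (SD, n = 6) (exact permutation p = 0.00476). The weighted libraries still did not overlap, with a gap of 1.60 percentage points, which argues against position as the whole of the difference; for a part, the test does not decide. The difference in the authors' pools was -12.7, with no replicates, so a share owed to reads left out of the library lists cannot be told apart from the effect of the genotype. Loss of Xrcc4 stays open as a biological explanation.

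For the bins, the libraries were also split in other ways into groups of the same sizes. Of 100 of the 126 splits for DNA-PKcs-/- against the controls, 1, the real one with 35 bins past the threshold, gave as many, and the highest other gave 27. For Xrcc4-/-, 1 of 100 gave as many, the real one with 48 bins, and the highest other gave 32. As the real split is among the 100, no share below 1 in 100 was possible. Counts as large as these were rare among the splits, but chance is not excluded. The highest other split in each case sets 4 control libraries against the mutant libraries and 1 control, close to the mirror of the real split. The splits do not exclude sequencing run for DNA-PKcs-/-, where 3 of the 4 libraries share run 2 and run as a covariate left 4 bins higher and 8 lower.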
